A study of Mus musculus with 12 samples.

How the data were processed

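Gene expression was measured in CD4+ T cells of mice on 12 Affymetrix Mouse Genome 430 2.0 arrays, 3 in each of 4 groups. Per the labels' protocols, RNA was isolated with RNeasy and labelled with biotin by in vitro transcription under the manufacturer's standard protocol. The deposited values are linear intensities, one per probe set and array, for 45101 probe sets. The software and the normalization behind these intensities are not given in the sources used here.

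The median deposited intensity per array ran from 15.7 to 27.6, a ratio of 1.76 over the 12 arrays. Among the 6 transfer arrays alone the ratio was 1.21. A rule set before the data were examined asked for quantile normalization where the ratio exceeded 1.5. The ratio over all 12 arrays was used, so the arrays of each comparison, also the transfer arrays, were quantile normalized together. They entered without the 64 control probe sets and as log2(intensity + 16). A fold change is therefore on the log2(intensity + 16) scale, which understates the change of dim genes. The added constant and the number of arrays limit the precision, and no depth applies to arrays.

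The probe annotation listed 1 gene for 34958 probe sets, several for 932 and did not list 9160, which are unnamed here. Symbols were updated by gene ID to the mouse assembly GRCm38.p6 for 34754 probe sets. No coordinates are given, since no build is named for the array. The brightest probe set over the 12 arrays stood for each of 18193 genes. A gene was tested where its mean over the 6 arrays of a comparison reached the 40th percentile of all probe sets. Several genes of the lists fixed in advance, among them members of the Th17 list, are not analysed here.

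Each comparison was fitted on its own 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjusted p under 0.05. The difference between the comparisons was tested as an interaction over all 12 arrays. Overlaps were tested with a one-sided Fisher exact test. The 30 gene lists, also fixed in advance, were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over 54 tests in both comparisons. A list needed 3 tested members, and 3 lists in each comparison had fewer.

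Genes are named by a rule fixed in advance. It took the 10 largest rises and falls per comparison among passing genes whose groups did not overlap, a fixed set of cytokine and lineage genes, up to 4 members of each list described with the smallest p, genes passing in the same direction in both comparisons, and the 6 genes with the smallest interaction p. A list is described where its test passed with or without the replicate block, a choice made after the data were seen.

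The labels number the replicates 1 to 3 in every group, and the numbers were checked for pairing. Deviations from the group mean of same-numbered arrays correlated across genes at 0.13, 0.20 and 0.33 between SKG and BALB, and at 0.46, 0.45 and 0.70 between the transfer groups. All were over 0.1, the value set in advance for treating the numbers as pairs, so values from a fit with the replicate number as a block are given where they change the call of a result described or move its count by over 1.5 times. Most of this structure set replicate 3 against replicates 1 and 2. Replicate 1 of either group correlated with replicate 2 of the other at 0.17 and 0.17 between SKG and BALB. Between the transfer groups these values were 0.44 and 0.41. The numbers therefore do not show pairs within replicates 1 and 2, and the block acts mainly on replicate 3. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these arrays, which may be technical.

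The fits were tested on simulated data built from the real means, replicate effects and spreads, with 200 genes changed. For SKG vs BALB, over 12076 genes, the fit without the block recovered 35% of genes changed by 1 on the log2 scale and 94% of those changed by 2. For the transfer comparison, over 12260 genes, it recovered 19% and 80%. The blocked fit recovered 87% and 100% for SKG vs BALB, with 25 unchanged genes called, and 89% and 100% for the transfer comparison, with 11 unchanged genes called. The fit without the block called 0 unchanged genes in either simulation. The simulated arrays of the same number shared 1 replicate effect in both groups, and their noise was taken from the blocked fit. Both choices favour the blocked fit, so these shares do not show which fit suits the real arrays.

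The alternatives were other added constants (1 and 64), no filter and a 60th percentile filter, no normalization, the median of a gene's probe sets, all probe sets separately, a fit without the trend, all 12 arrays in one fit, the replicate block, array weights, leaving out each array in turn, and for lists an estimated correlation and fry. Scaling to a trimmed mean, a batch block setting replicate 3 against replicates 1 and 2, and replicates 1 and 2 alone were added after seeing the data.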

Results

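Transcript levels were compared in CD4+ T cells from female mice in a series on Th17 cells, the IL-17-producing helper lineage. Cells of SKG mice, a BALB/c-background strain with a point mutation in the T cell receptor kinase gene Zap70, and of BALB/c mice were taken at 40 weeks and are labelled as stimulated with PMA and ionomycin. They were sorted without FR4, the folate receptor encoded by Izumo1r, except that BALB replicate 1 is labelled as CD4+ cells from spleen and lymph node without that sort. The other groups were spleen cells 7 days after CD4+ T cells were transferred into lymphocyte-deficient hosts, labelled either as IFN-γ-deficient cells into RAG2-deficient hosts or as IL-6-deficient cells into hosts lacking both IL-6 and RAG2. Their labels give an age of 7 weeks, so age differs from the SKG and BALB groups together with the labelled stimulation. Each group had 3 arrays. The trimmed mean intensity ran from 161 to 232 over the 12 arrays.

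The genes named in the labels were read first. In the arrays labelled IFN-γ-deficient, Ifng was 9.41 ± 0.47 (SD, n = 3) on the log2 scale against 13.56 ± 0.02 in the arrays labelled IL-6-deficient, a fall of 4.15 by limma (adjusted p = 0.0011), and it stayed above the tested floor of 4.72. Il6 was not lower in the arrays labelled IL-6-deficient, at 6.51 ± 1.33 against 5.38 ± 1.27 (limma adjusted p = 1.0, and 0.015 with the replicate block). With the 12 arrays normalized together, Il6 was 4.56 and 4.77 in IFN-γ-deficient replicates 1 and 2, near that floor, and 6.84 in replicate 3. Such levels left little room for a lower one, so Il6 does not check the IL-6 label. The labels do not say which part of either gene was deleted, and a probe set outside it checks nothing. Zap70 fell by 0.60 in SKG arrays (limma adjusted p = 0.014), a call lost without BALB replicate 1 (adjusted p = 0.067), without BALB replicate 2 (0.059) and without SKG replicate 1 (0.060), and with all 12 arrays in one fit (0.11).

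SKG cells held more transcript of most tested Th17 genes than BALB cells. Il17a, the defining Th17 cytokine, rose from 7.99 ± 0.57 to 12.91 ± 0.12 (SD, n = 3), a log2 fold change of 4.92 ± 0.25 (SE, limma adjusted p = 1.8e-05). Il21 rose by 3.27 ± 0.17, Ccr6, a chemokine receptor of Th17 cells, by 2.92 ± 0.19, and its ligand Ccl20 by 3.65 ± 0.60. Of the 11 tested members of the Th17 list 9 rose and 0 fell, also 9 when adjusted over the list alone, with a median of 3.27 (camera adjusted p = 1.3e-06). With an estimated correlation the adjusted p = 0.13. Il1r1, an interleukin-1 receptor, rose by 3.56 ± 0.24 (SE) and Tmem176a by 3.45 ± 0.22.

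**Figure D1:**
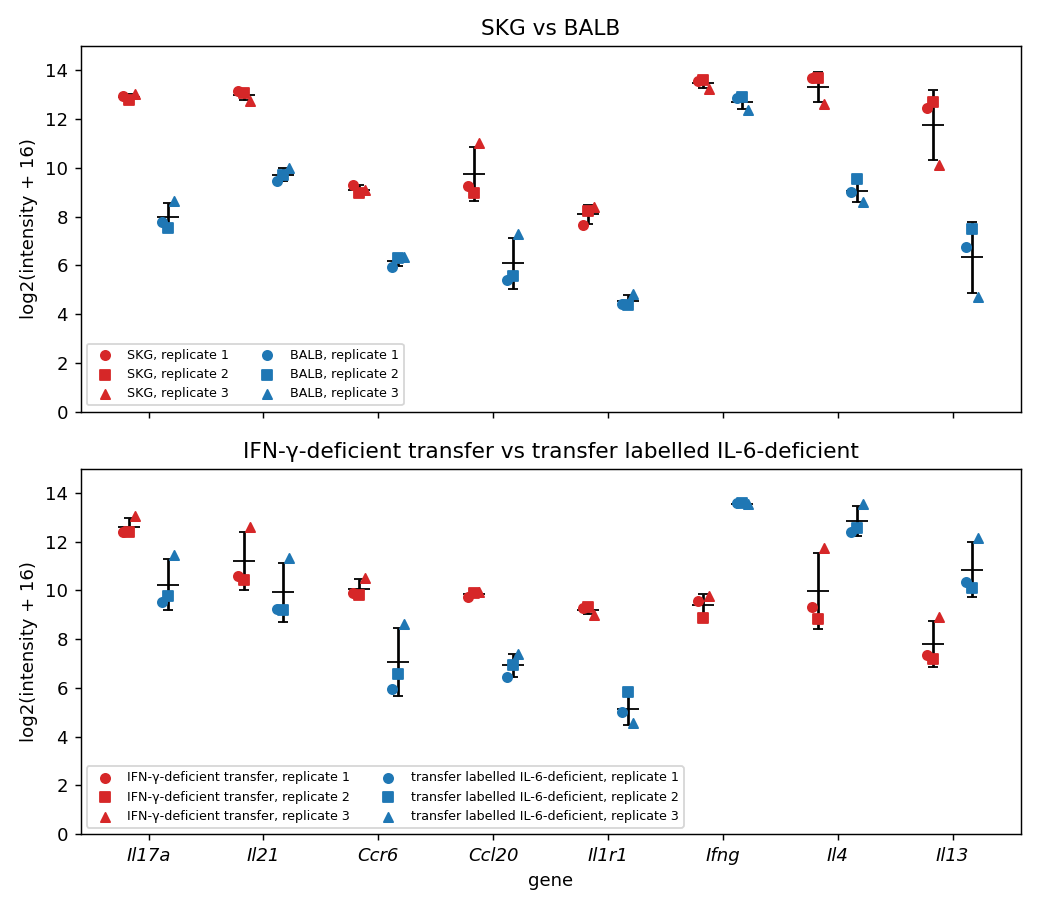
Log2(intensity + 16) of 8 genes in each array, with SKG and BALB above and the transfer groups below. Circles, squares and triangles are replicates 1, 2 and 3, and black bars are the mean and SD of 3 arrays. Il17a lies at 12.91 in SKG against 7.99 in BALB, and Ifng at 9.41 in the IFN-γ-deficient transfer against 13.56 in the transfer labelled IL-6-deficient.

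The rise was not confined to Th17 genes. Il13 rose by 5.43 ± 0.80 (SE), Il4 by 4.28 ± 0.31, Il9 by 3.81 ± 0.55 and Il10, a regulatory cytokine, by 4.56 ± 0.89 (limma adjusted p between 8.8e-05 and 0.0058). Of 8 tested Th2 members 6 rose and 0 fell, the same counts when adjusted over the list alone (camera adjusted p = 0.010), with an adjusted p = 0.47 with an estimated correlation. 1 Th2 member fell with the replicate block. The call was lost without BALB replicate 3 (adjusted p = 0.059). Of 9 Th1 members 7 rose and 2 fell, again the same counts adjusted over the list alone (camera adjusted p = 0.049, and 0.47 with an estimated correlation), among them Cxcr3, up 2.47 ± 0.22, and Tbx21, the Th1 regulator, which fell by 1.07 ± 0.12. The Th1 call was lost without BALB replicate 3 (adjusted p = 0.071), with a 60th percentile filter (0.082) and with log2(intensity + 64) (0.050). Ifng itself rose by 0.75 ± 0.16 (limma adjusted p = 0.0087), a call lost without normalization between arrays (adjusted p = 0.083).

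Genes of effector cells rose and genes of naive cells fell in SKG. Of 12 cytotoxic members 9 rose and 1 fell (camera adjusted p = 0.00023, and 0.37 with an estimated correlation), with Gzmb up 3.20 ± 0.22 and Gzma up 3.07 ± 0.17. Of 14 effector and memory members 10 rose and 1 fell (camera adjusted p = 0.00023, and 0.37 with an estimated correlation), with Cxcr6 up 3.68 ± 0.23 and Lgals1 up 2.33 ± 0.23. Of 11 naive members 6 fell and 2 rose (camera adjusted p = 0.020, and 0.50 with an estimated correlation), where Klf2 fell by 3.23 ± 0.32 and the lymph node homing receptor Ccr7 fell by 3.19 ± 0.33, while Il7r rose by 1.58 ± 0.15. The naive call was lost without BALB replicate 3 (adjusted p = 0.059), with a 60th percentile filter (0.052) and by fry (0.090). Adjusted over the list alone, 10 cytotoxic, 10 effector and 2 naive members rose and 1, 1 and 7 fell.

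Genes of regulatory and follicular cells also rose. Of 11 Treg members 9 rose and 0 fell (camera adjusted p = 0.0024, and 0.37 with an estimated correlation), with Ikzf2 up 2.76 ± 0.31, Ctla4 up 2.53 ± 0.41 and Foxp3, the regulator of Treg cells, up 1.74 ± 0.21. Ikzf2 lost its call with the median of its probe sets (adjusted p = 0.054). Izumo1r, the gene of the sorted-out receptor, rose by 0.84 ± 0.18. Of 9 Tfh members 7 rose and 0 fell (camera adjusted p = 0.0016, and 0.37 with an estimated correlation), with Icos up 1.60 ± 0.12. Adjusted over the list alone, 9 Treg and 8 Tfh members rose and 2 and 1 fell, and with the replicate block 2 and 1 also fell. Of 10 coinhibitory members 6 rose, with Havcr2 up 3.02 ± 0.58, and of 15 chemokines 7 rose and 1 fell, with Ccl1 up 4.22 ± 0.32 (camera adjusted p = 0.020 and 0.026, and 0.42 and 0.37 with an estimated correlation). Adjusted over the list alone the counts were the same in both. Both calls were lost without BALB replicate 3 (adjusted p = 0.071 and 0.066), the coinhibitory call with a 60th percentile filter (0.083) and the chemokine call with no filter (0.053).

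Genes induced by IFN-γ fell in SKG. Of 17 tested members 8 fell and 0 rose, 11 and 0 when adjusted over the list alone (camera adjusted p = 0.0013, and 0.42 with an estimated correlation). Cxcl10 fell by 2.60 ± 0.26 and Irf1 fell by 1.14 ± 0.10 (SE). Among the largest falls, Bex1 fell by 4.13 ± 0.18 (SE), Xkrx fell by 3.77 ± 0.41, Itm2a fell by 3.59 ± 0.16 and Sox4 fell by 3.41 ± 0.16. Aqp9 rose by 3.69 ± 0.30, Cysltr1 by 4.25 ± 0.36 and Ccr2 by 4.16 ± 0.38. Other probe sets above the floor had the same sign but some were smaller. They ran from -3.41 to -0.99 for Sox4 (6 probe sets), 1.60 to 3.69 for Aqp9 (2) and 1.46 to 4.16 for Ccr2 (4). Those of Itm2a, from -3.76 to -3.59, and Cysltr1, from 4.18 to 4.25, lay close together.

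Over all 12076 genes tested, 1901 were higher and 1420 lower in SKG by limma, 724 and 626 of them by at least 2-fold. Without normalization between arrays 1131 were higher and 829 lower. Without BALB replicate 1, the array without the FR4 sort, 1256 were higher and 874 lower, without SKG replicate 1 they were 1114 and 886, and without SKG replicate 2 they were 1157 and 905. Array quality also separated the groups. The actin 3'/5' signal ratio was 2.12, 1.93 and 2.63 in SKG replicates 1 to 3 against 3.04, 2.95 and 3.98 in BALB. The poly-A spike-in signal relative to the hybridization controls (log2) was -1.79, -1.53 and -1.81 against -1.08, -1.05 and -1.50. Gapdh 3'/5' ratios overlapped. How far this adds to the gene counts was not tested. Of markers of other cell types, Ighm of B cells rose by 1.94 ± 0.44 to 12.16 ± 0.65 (SD, n = 3), Derl3 of plasma cells by 0.80 ± 0.20, and Cd8b1 fell by 2.49 ± 0.43. The value for Ighm is the highest of its 8 probe sets above the floor, which ran from -0.22 to 1.94, with 7 of them higher in SKG. Of 10 B cell members 1 rose, of 4 plasma cell members 2, of 5 dendritic members 1, and of 9 macrophage, 4 neutrophil, 4 erythroid and 3 stromal members 0. Of macrophage members 1 rose and 1 fell with the replicate block, and 0 dendritic members passed. None of these lists passed camera, while the B cell list, with a median of 0.46, passed with replicates 1 and 2 only (adjusted p = 0.042). Of 2 CD8 members 1 fell and the 1 mast cell member tested did not pass, lists too small for camera, and no NK member reached the filter. Adjusted over the list alone, 1 CD8 member rose and 1 fell, and 3 plasma cell members rose and 1 fell. Probe sets of Cd8a above the floor ran from -0.11 to 0.81 and those of Sdc1, a plasma cell member, from -1.19 to -0.64.

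**Figure D2:**
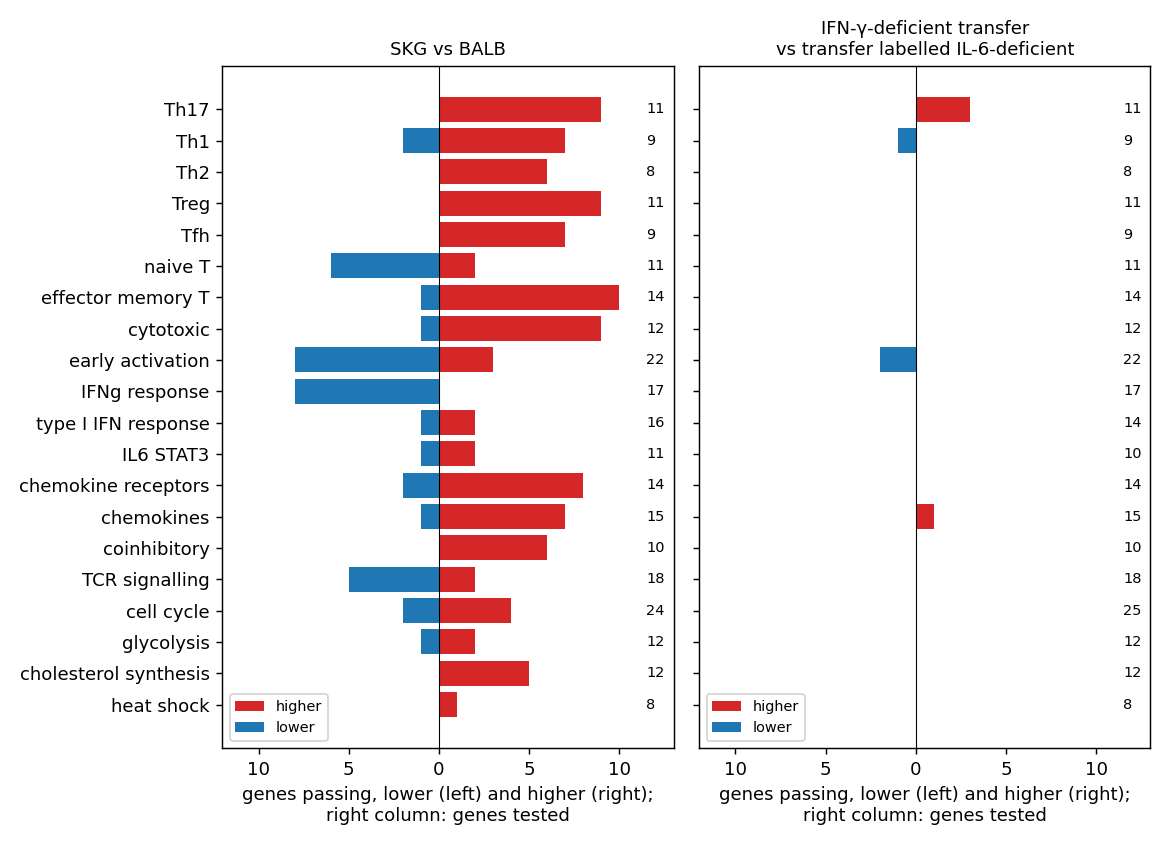
Number of members of each T cell and pathway list that passed limma in SKG vs BALB (left panel) and in the transfer comparison (right panel), with lower genes to the left of 0, higher genes to the right, and the number tested at the edge. In SKG 9 of 11 Th17 members were higher, and 3 of 11 in the IFN-γ-deficient transfer.

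In the transfer comparison fewer genes passed, and several belonged to the same Th17 list. No transfer of unmodified cells was included, and donor and host genotype differed together. Rose and fell here mean higher and lower in the IFN-γ-deficient transfer, without saying which group changed. Relative to the transfer labelled IL-6-deficient, a label that the Il6 level did not check, the IFN-γ-deficient transfer held more Il1r1, the interleukin-1 receptor, by 4.06 ± 0.33 (SE), Serpinb1a by 3.14 ± 0.25, Ccl20 by 2.92 ± 0.25, Tmem176a by 2.08 ± 0.24 and Mid1 by 2.87 ± 0.26 (limma adjusted p between 0.0086 and 0.042). Il17a was 12.62 ± 0.37 (SD, n = 3) against 10.24 ± 1.05 and the log2 fold change of Ccr6 was 3.02 ± 0.64 (SE). Neither passed (limma adjusted p = 0.38 and 0.40), and both passed with the replicate block (adjusted p = 0.00074 and 0.0020). Serpinb1a lost its call with the median of its probe sets (adjusted p = 0.16), and Tmem176a lost its call under 6 other settings of processing (adjusted p from 0.055 to 0.14). Of 11 Th17 members 3 rose and 0 fell, 7 when adjusted over the list alone and 8 with the replicate block (camera adjusted p = 2.6e-15). With an estimated correlation the adjusted p = 0.13.

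Genes that fell in the IFN-γ-deficient transfer included Ifng, and Ifitm3 fell by 2.47 ± 0.21 (SE), Ifitm2 fell by 1.97 ± 0.19, Il3 fell by 1.78 ± 0.15, Fn1 fell by 1.64 ± 0.17 and Csf2 fell by 1.31 ± 0.10 (limma adjusted p between 0.0086 and 0.025). With all 12 arrays in one fit Il3 and Csf2 lost their call (adjusted p = 1.0 and 0.19), Csf2 lost it without the intensity trend (0.064), and Fn1 lost it with no filter (0.083), without normalization (0.067) and with the median of its probe sets (0.41), where its value was -0.86. Of 17 IFN-γ response members 0 passed, 2 fell when adjusted over the list alone and 4 fell with the replicate block, among them Gbp2 with a log2 fold change of -1.45 ± 0.35 (adjusted p = 0.52, and 0.0029 with the block), while the list passed (camera adjusted p = 2.4e-06, and 0.30 with an estimated correlation), a call lost by fry (adjusted p = 0.063). Of 8 Th2 members 0 passed, 3 fell when adjusted over the list alone and 5 fell with the block, with values of -3.04 ± 0.64 for Il13 and -2.87 ± 0.72 for Il4 (limma adjusted p = 0.40 and 0.58, with the block 3.4e-06 and 0.0016), and the list passed (camera adjusted p = 0.0013, and 0.30 with an estimated correlation). The Th1 list passed (camera adjusted p = 0.00049, and 0.35 with an estimated correlation), with 1 of 9 members, Ifng, lower and 3 lower when adjusted over the list alone. Ifng is the gene that the IFN-γ-deficient cells lack by their labels, and the list was not tested without it. Ifng and Stat4 (adjusted p = 0.032) were lower and Cxcr3 higher (0.021) with the replicate block. Of 22 early activation members 2 fell, Csf2 and Il3, also 2 when adjusted over the list alone and 7 with the block (camera adjusted p = 0.00080, and 0.47 with an estimated correlation), a list call lost without replicate 3 of the transfer labelled IL-6-deficient (adjusted p = 0.18) and by fry (0.29).

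With the replicate block 3 further transfer lists passed (camera), none with an estimated correlation (adjusted p = 0.51, 0.51 and 0.59). They were the Treg list (adjusted p = 0.017), the chemokine receptors (0.031) and the cholesterol synthesis list (0.022), of whose members 1, 3 and 1 rose. These also passed without the block when replicate 3 of the transfer labelled IL-6-deficient was left out (adjusted p = 0.018, 0.0039 and 0.033), as did the chemokine receptors without replicate 1 of the IFN-γ-deficient transfer (0.04999). Foxp3 was 10.73 ± 0.25 against 10.51 ± 0.15 (SD, n = 3; limma adjusted p = 1.0).

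Over 12260 genes tested, 8 were higher and 6 lower by limma, with 532 at an unadjusted p under 0.05. With the replicate block 95 were higher and 124 lower, including all 14. Without replicate 1 of the IFN-γ-deficient transfer 1 was higher and 1 lower, and without its replicate 2 these were 2 and 2. Without replicates 1, 2 and 3 of the transfer labelled IL-6-deficient in turn 2, 3 and 16 were higher and 3, 1 and 10 lower. Of the 14 genes 2, AI506816 and Ifng, passed without each array in turn, and the other 12 lost their call without replicate 1 of the IFN-γ-deficient transfer (adjusted p from 0.065 to 0.30). Of the lists of other cell types none passed camera and 0 members passed. The plasma cell gene Derl3 rose by 0.98 with the replicate block (adjusted p = 0.021). Single lists passed under other settings, plasma cell genes without replicate 2 of the IFN-γ-deficient transfer (adjusted p = 0.019), dendritic genes without replicate 2 of the transfer labelled IL-6-deficient (0.031) and with the median of probe sets (0.045), stromal and neutrophil genes without replicate 3 of the transfer labelled IL-6-deficient (0.039 and 0.0011), and neutrophil genes with replicates 1 and 2 only (0.022).

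The mean of Il17a was higher in the first group of both comparisons, and 6 genes rose in both, where 1.31 were expected if genes were independent (one-sided Fisher exact p = 0.00040 over 11433 genes). Genes are not independent replicates, so this p-value does not measure chance between arrays. They were Il1r1, Serpinb1a, Ccl20, Tmem176a, Pxdc1 and Acpp. In the transfer comparison Acpp lost its call with no filter (adjusted p = 0.083), without normalization (0.089), with the median of its probe sets (0.59) and with all probe sets separately (0.079), and Pxdc1 with no filter (0.066). Of the 10 genes that passed in both comparisons the other 4 went opposite ways, higher in SKG and lower in the IFN-γ-deficient transfer, and with the replicate block 45 of 141 went opposite ways. Without replicates 1 and 2 of the IFN-γ-deficient transfer in turn 0 and 1 rose in both, and without replicates 1 and 2 of the transfer labelled IL-6-deficient 1 and 2. With the replicate block 50 genes rose in both against 19.6 expected. No gene fell in both by limma, with 46 falling in both with the block against 18.3 expected. Across genes, which are not independent replicates, the log2 fold changes correlated weakly (Pearson r = 0.14, Spearman rho = 0.16). Without replicate 3 of the transfer labelled IL-6-deficient r was 0.034, and without replicate 2 of the IFN-γ-deficient transfer it was 0.081. A change differed between the comparisons for 1010 genes in the limma interaction test, and for 3102 with the replicate block. Without single arrays that number was 583 and 650 (BALB replicates 1 and 3), 534 and 522 (SKG 1 and 2), 632 and 668 (IFN-γ-deficient 1 and 2), and 589, 552 and 1521 (labelled IL-6-deficient, 1, 2 and 3). The difference was 8.48 for Il13 and 7.14 for Il4 (limma interaction adjusted p = 0.0016 and 0.00070), which rose in SKG.

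**Figure D3:**
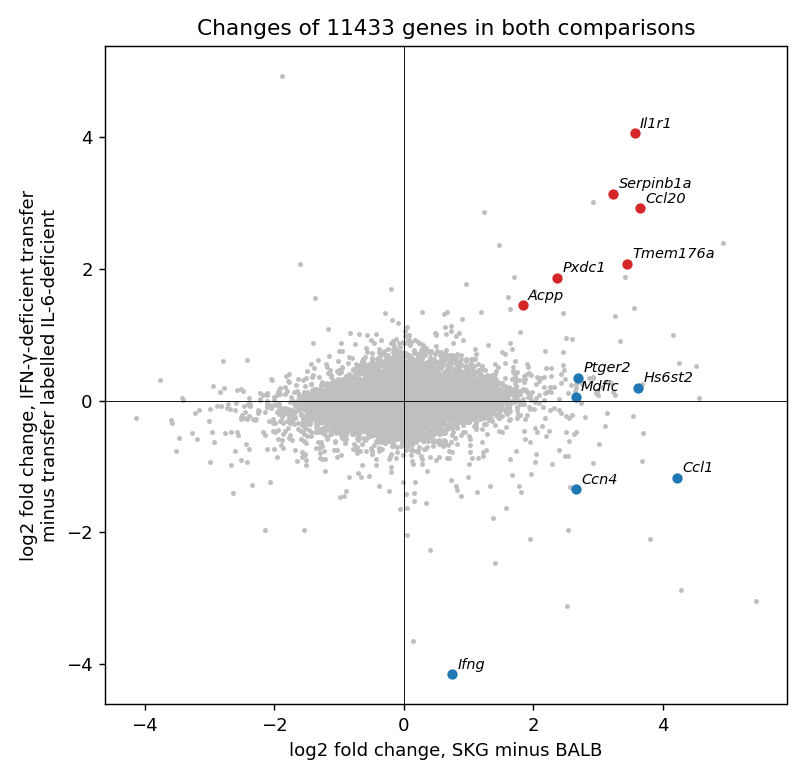
Log2 fold change of 11433 genes in SKG minus BALB (horizontal) and IFN-γ-deficient transfer minus the transfer labelled IL-6-deficient (vertical). Red points are the 6 genes that rose in both and blue points the 6 with the smallest interaction p. Il1r1 lies at 3.56 and 4.06, and Ifng at 0.75 and -4.15.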

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

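The tests of replicate 3 were chosen only after the result was seen. The splits and regroupings were set before their results were seen.

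The change of 1010 genes differed between the comparisons in the limma interaction test. The difference, SKG minus BALB less the transfer difference, was 4.93 for Ifng, which the labels say is deleted in one transfer group, 5.33 for Ccl1, 4.01 for Ccn4, 3.45 for Hs6st2, 2.57 for Mdfic and 2.31 for Ptger2. Of 100 regroupings of both comparisons 7 gave as many genes, the highest other giving 1577. All 7 were among the 9 that kept the real SKG and BALB groups, and those that did not gave at most 2, so this share was set by whether those groups were kept and does not test chance.

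Probe sets without a single gene name, which the comparisons leave out, also changed, with 410 of 4823 passing between SKG and BALB and 1 of 4642 between the transfer groups.

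The 3321 genes called between SKG and BALB compare with 0 in the highest other split of the 6 arrays, and the 14 between the transfer groups also with 0. In each, 1 of 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05. With the replicate block the real splits gave 4171 and 219, and the 3 others that part every pair gave 0. For genes changed the same way in both comparisons, 1 of 100 regroupings, the real one, gave as many as 6, the highest other giving 4, which was the real groups with the direction of the transfer comparison turned. Since every other split of either comparison called 0 genes, this share was fixed by the splits and does not test chance. For list tests 7 of 100 gave as many as 16, the highest other giving 19, which does not exclude it. All 7 kept the real SKG and BALB groups. The median of the other regroupings was 7 list tests, with up to 13 where those groups were broken. The correlation of fold changes, 0.14, was reached by 17 of 100 regroupings.

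Replicate 3 stood apart from replicates 1 and 2 in all 4 groups. In the transfer groups its poly-A spike-in signal relative to the hybridization controls was lower by 2.25 (log2, a difference of -2.248) and its Gapdh 3'/5' ratio higher by 6.05, both outside the other 4 arrays, which is consistent with a separate labelling batch and with RNA labelled mostly at the 3' end. In SKG and BALB its trimmed mean intensity was higher by 57.5, which also goes with a separate batch, while the Gapdh ratio differed by -0.096 and the actin ratio was higher within both groups, so a 3' bias stays open there. The poly-A measure did not clearly set replicate 3 apart in these groups. It was -1.81 in SKG replicate 3 against -1.79 in SKG replicate 1. BALB replicate 3, at -1.50, was lowest in its group but within the range of the other 4 arrays. Single genes set SKG replicate 3 apart where BALB replicate 3 was near its group. With the 12 arrays normalized together, Il3 was 12.37, 11.96 and 7.98 in SKG replicates 1 to 3, against 9.15, 9.49 and 9.53 in BALB. A difference between mice was not tested.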

How the results depend on the processing

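Trimmed mean scaling, the batch block and replicates 1 and 2 alone were chosen after seeing the data, and the cause of a change was not tested unless named. Of the results recomputed singly, named genes between SKG and BALB kept their call in 1288 recomputations and lost it in 8, and transfer genes kept theirs in 213 and lost it in 65. The 6 interaction genes kept theirs in all 148. These were chosen by the smallest p, and other named genes by size or p, in these same data. That choice favours keeping a call, so the tallies do not speak for other genes. Counts of SKG vs BALB genes moved to 1131 higher and 829 lower without normalization, to 2917 and 2207 with array weights and to 2866 and 2204 with replicates 1 and 2 only, and to 2465 lower with all probe sets separately, where more features are tested. Leaving out 1 array gave 1114 to 2192 higher and 874 to 1715 lower. Transfer genes were 95 higher and 124 lower with the replicate block, 164 and 188 with the batch block, 96 and 91 with array weights, 262 and 239 with replicates 1 and 2 only, and 22, 5 and 4 higher with 12 arrays in one fit, no filter and the median of probe sets. Leaving out 1 array gave 1 to 16 higher and 1 to 10 lower.

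Genes higher in both comparisons were 50 with the replicate block, 80 with the batch block, 45 with array weights, 144 with replicates 1 and 2 only, 14 with 12 arrays in one fit, 3 with no filter and 3 with the median of probe sets, and 0 to 9 leaving out 1 array. Genes lower in both were 46, 75, 26 and 102 under the first 4. Genes differing between the comparisons were 3102, 3630, 3783 and 3758 under these, 427 without normalization, and 522 to 1521 leaving out 1 array. The correlation of fold changes ran from 0.034 to 0.19 leaving out 1 array. Of the 16 list tests 0 passed with an estimated correlation. Among all genes named by rule, the replicate block added 25 of 124 transfer calls, and between SKG and BALB added 5 of 127 calls (Bst2, Cd68, Cst3, Il4ra and Pgam1, adjusted p from 0.0079 to 0.039) and ended 1 (Zbtb46, 0.055). It added 3 list calls, all in the transfer comparison, and changed no other call of a named gene or list.

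Signs changed in 150 of 6054 recomputed values of 311 genes and lists, none of them called in the reported fit and 2 of them called in the alternative. Those 2 are the neutrophil list in the transfer comparison, with a median of 0.70 with replicates 1 and 2 only and from -0.55 to 0.85 leaving out 1 array. That list was 0.035 with log2(value + 1), 0.019 without normalization and 0.062 with trimmed mean scaling. Among other transfer values the text or its lists use, Il10 was -0.091 without normalization and -0.68 to 0.76 leaving out 1 array, Mdfic was -0.065 without normalization, -0.00012 with array weights, -0.030 with replicates 1 and 2 only and -0.018 to 0.12 leaving out 1 array, and Zap70 was 0.18 with the median of probe sets and -0.53 to 0.013 leaving out 1 array. List medians were -0.0073 for effector and memory genes without normalization, -0.096 for stromal genes with no filter, and 0.026 and 0.027 for naive and cell cycle genes with replicates 1 and 2 only. Leaving out 1 array they ran from -0.37 to 0.11 for naive, -0.26 to 0.12 for cell cycle, -0.57 to 0.068 for cytotoxic, -0.34 to 0.63 for plasma cell and -0.11 to 0.50 for stromal genes. Sign changes of lists that passed under no setting, and of list members named only for a list not described, are in the totals and not given singly, a choice made after the data were seen.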

Other observations

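The comparison of early activation levels, also by replicate, and the test around Il6 were chosen only after the result was seen. The test without normalization and the test around Ifng were set before.

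Several lists that did not pass camera between SKG and BALB held members that changed there, where 8 of 14 chemokine receptors rose and 2 fell, 5 of 12 cholesterol synthesis members rose, 5 of 18 T cell receptor signalling members fell and 2 rose, 4 of 24 cell cycle members rose and 2 fell, and 3 of 22 early activation members rose and 8 fell, where Fosb fell by 1.94 ± 0.22 (SE) and Csf2 rose by 2.57 ± 0.36. Of type I interferon response members 2 of 16 rose and 1 fell. Oas1a, of that list, rose by 4.51 ± 0.25 (SE). Of glycolysis members 2 of 12 rose and 1 fell, of heat shock members 1 of 8 rose, and of IL-6/STAT3 members 2 of 11 rose and 1 fell. The replicate block gave 3 IL-6/STAT3 and 2 glycolysis members lower. The early activation list passed by fry (adjusted p = 0.011), as did the chemokine receptors (0.0075) and cholesterol synthesis (0.0495). Without SKG replicate 1 these 3 lists passed camera (adjusted p = 0.042, 0.033 and 0.042), as did the chemokine receptors without BALB replicate 1 (0.046). The chemokine receptors also passed camera without normalization (adjusted p = 0.012) and with log2(intensity + 64) (0.049). Early activation genes passed camera with log2(intensity + 64) (adjusted p = 0.0499) and the median of probe sets (0.040), and cholesterol synthesis with no filter (0.043).

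Between the transfer groups cytotoxic, naive and coinhibitory genes passed camera without replicate 3 of the IFN-γ-deficient transfer (adjusted p = 0.00012, 0.027 and 0.018), and cell cycle genes without its replicate 2 (0.014). Type I interferon response genes passed without replicate 1 (0.035) or 3 (0.038) of the IFN-γ-deficient transfer and without replicate 1 of the transfer labelled IL-6-deficient (0.0497). The replicate block gave 2 cytotoxic, 2 chemokine, 1 glycolysis and 1 effector and memory member lower between the transfer groups, and 1 each of Tfh, T cell receptor signalling and effector and memory members higher. The median, mean and test were not of one sign for T cell receptor signalling, glycolysis and stromal genes between SKG and BALB, and for chemokine, heat shock and neutrophil genes between the transfer groups.

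The labels of the transfer arrays mention no stimulation, yet over 22 early activation genes their median level was 0.75 below the PMA and ionomycin arrays (a difference of -0.747), and 12 of 22 lay within 1 on the log2 scale, 7 at or below -1 and 3 at or above 1. Of those within 1, Il2, Nfkbia and Egr2 lay above the 99.3 percentile in all 12 arrays. Nearness at the top of the scale says little about them. For replicate 3, whose transfer arrays had the high 3'/5' ratio, the median was -0.14 against replicate 3 of SKG and BALB, with 16 of 22 within 1, and for replicates 1 and 2 it was -0.92, with 8 of 22 within 1. Without normalization these medians were -0.53 and -0.75, with 16 and 11 of 22 within 1, so the gap between replicates was smaller without it. Over all 12 arrays the median difference without normalization was -0.773, close to -0.747 with it. The rule set before took a median below -1 as the mark of normalization, and -0.773 was above that bound. By the rule as set, normalization thus did not account for the median. The members spread around the bound, a condition not in that rule, so a part of normalization in single genes is not excluded. An unrecorded stimulation may account for these levels, and so may activation in the host, and these cannot be told apart.

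AI506816 rose by 4.93 ± 0.22 in the IFN-γ-deficient transfer over the transfer labelled IL-6-deficient (limma adjusted p = 0.00066). It lies 30 tested genes from Il6, within the 50 on each side that were counted as neighbours, so DNA carried along with the targeted gene was a candidate explanation. Of 99 tested neighbours of Il6 2 passed with the replicate block, where 1.75 were expected (Fisher exact p = 0.52), and of 100 neighbours of Ifng 3 passed against 1.76 (Fisher exact p = 0.26). These values give the explanation no support and do not exclude it. AI506816 was also low in SKG replicates 1 and 2, at 6.79 and 7.19, against 10.69 in SKG replicate 3, although SKG is not labelled with a change of Il6.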
